A study of Homo sapiens with 92 samples.

How the data were processed

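RNA from 52 cancer and 40 non-cancer samples was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per sample, after 2-cycle labelling with biotin, per the labels' protocols. The deposited values were linear MAS5 signal intensities made with Affymetrix Expression Console 1.1, per the submitters' processing notes. On every array the mean signal after trimming 2% at each end was close to 500, so each array had been scaled by a single factor before deposit. A single factor does not bring arrays with different signal ranges onto a common scale, and differences between arrays in range stay in the values. Detection calls and scanner images were not used here, and no genome build or coordinates apply to the values used. The number of arrays limits the precision, and nothing in the labels says that samples came from separate donors, so p-values measure the spread between these samples.

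Probe sets were named from the platform annotation. Of 54675 probe sets, 62 were controls, 41097 had exactly 1 gene symbol, 1801 had several and 11721 were not listed. Of the 41097, 41043 matched a current gene by their gene identifier. Genes were named only from probe sets with 1 symbol. Values were analysed as log2 (signal + 16), without further normalization. Differences are on this scale, which understates those of weakly expressed genes. A probe set was kept when it exceeded the 60th percentile of its array on at least 20 arrays, whatever the group, which left 35619 probe sets. Each gene was represented by its probe set with the highest mean, giving 15210 genes.

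Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 31 of them with 508 genes of which 402 were measured, were tested with camera at a preset correlation of 0.01 and at an estimated one, with fry, and by 100000 two-sided permutations of the labels on the mean of each list. Differences of list means between kinds of array were tested with 20000 permutations within each kind. AUC was computed per gene. The signature was an L1-penalized logistic regression (glmnet 4.1.10) in 5-fold cross-validation repeated 10 times, with ranger 0.17.0 for the random forest. Correlations were tested with 100000 permutations. Figures were drawn with matplotlib.

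The named genes followed a rule fixed before the data were examined: the 12 largest differences in each direction among genes past the threshold with an AUC of at least 0.65 in that direction, or the 5 with the smallest p in a direction where none passed; every member of the 2 biomarker lists; and from each other list up to 2 members in each direction, or the 2 with the smallest p where none passed. XIST, TSIX and Y-linked genes were left out of all named genes and plots. The groups, the tests over all 92 arrays and the lists were fixed at the same time. The split of arrays by signal range, its limit of 32 and every test in wide-range or narrow-range arrays were chosen after seeing the data. The naming rule was then applied to the wide-range arrays with a change. From each list other than the biomarker lists, the members with the smallest p among those past the threshold were taken, whatever their direction. Of 135 named genes, 55 had several probe sets that passed the filter, and for 9 of these the probe sets differed in sign in the wide-range arrays.

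The fits were tested on the real arrays with permuted labels and shifted values, 250 genes for each size of shift over 5 draws. Over all 92 arrays, 57.6% of genes shifted by 1 on the log2 scale were recovered, 98.8% of those shifted by 2 and 100% of those shifted by 3, with 2.8 other genes called on average among 15210. In the 28 wide-range arrays the shares were 26.8%, 91.2% and 99.6%, with 1.4 other genes called on average. Many genes were shifted at once in each draw, which loosens the adjusted threshold. Where few genes pass, as in the real comparison over all 92 arrays, a shift of the same size would be recovered less often. Alternatives tried were quantile normalization, centring on the median, other pseudocounts and filters, other choices of probe set, moderated tests with trend or array weights, a Wilcoxon test, covariates for the 3'/5' ratio of control probe sets and for leukocyte genes, a block on the sample number, leaving out each array, and leaving out 1 of the 2 most similar arrays. The part of a difference that goes with a covariate is the unadjusted minus the adjusted difference, with an interval from 5000 stratified bootstrap draws.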

Results

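Gene expression was measured in cells collected from the human bladder, 52 samples labelled as urothelial cancer and 40 labelled as non-cancer, with 1 Affymetrix Human Genome U133 Plus 2.0 array per sample. The sample source is given as bladder barbotage, a forceful washing of the bladder that dislodges cells from its lining, while another label speaks of urine sediment, so the collected material can hold urothelial cells, blood leukocytes and squamous cells. By its title the series was made to find a set of markers for detecting bladder cancer, and the labels give a single comparison, cancer against non-cancer. Of 54675 probe sets, 41097 carried exactly 1 gene symbol, and 15210 genes were tested.

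The arrays differed widely in signal range, taken as the 99th percentile of the signal over its median. This ratio went from 7.28 to 145, with a median of 13.02. It exceeded 32 on 28 arrays, called wide-range arrays here, and reached at most 28.02 on the other 64, the narrow-range arrays. Wide-range arrays made up 16 of 52 cancer samples (30.8%, 95% exact binomial interval 18.7 to 45.1) and 12 of 40 non-cancer samples (interval 16.6 to 46.5; Fisher's exact test, two-sided p = 1). The first principal component held 42.3% of the variance, and its correlation with the log2 range across the 92 arrays had an absolute value of 0.978. The median correlation between arrays (Pearson, log2 signal) was 0.775 among wide-range arrays and 0.492 among the others. With each gene centred within wide-range and within narrow-range arrays, 2 narrow-range non-cancer arrays had a correlation of 0.850, against 0.636 for the next pair of narrow-range arrays and a median of -0.0167 over all pairs. The next highest of all pairs, at 0.768, joined a cancer and a non-cancer array, both wide-range. The labels do not say that the arrays of either pair hold the same specimen, and all are counted in their groups. The dividing value was chosen after the data were seen. Limits of 4, 4.5 and 5 on the log2 scale were tried while exploring, and they left 41, 32 and 28 arrays with 0, 4 and 30 genes past the limma threshold; 5 corresponds to the ratio of 32 and was kept. The comparison over all 92 arrays was fixed in advance, and the values in wide-range arrays are given beside it as an addition.

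**Figure D1:**
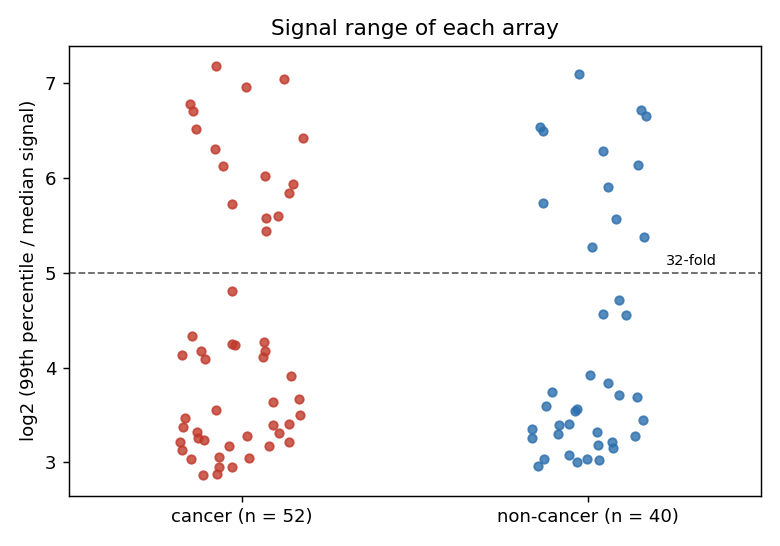
Signal range of each array, as the log2 ratio of the 99th percentile to the median signal, for 52 cancer and 40 non-cancer samples. Each point is an array and the dashed line marks a ratio of 32; 16 cancer and 12 non-cancer arrays lie above it.

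Over all 92 arrays, MMP12, which encodes the macrophage elastase of the matrix metalloproteinase family, was the gene that rose in cancer. Its mean log2 signal was 1.73 higher in cancer (SE 0.349, n = 52 and 40, limma adjusted p = 0.0446), a 3.32-fold difference on the scale of signal + 16. It lay above the non-cancer median in 45 of 52 cancer samples and above every non-cancer sample in 11. No gene passed the test in the other direction. The 5 lower genes with the smallest p did not pass: RAP1GAP, a GTPase-activating protein (log2 difference -0.70), POMGNT2, an enzyme of protein O-mannosylation (-0.86), AXIN2, a feedback inhibitor of Wnt signalling (-0.80), and the zinc finger genes ZNF667 (-0.61) and ZNF689 (-0.73), with limma adjusted p of at least 0.678. At an unadjusted p under 0.05 there were 491 genes, fewer than the 760.5 that chance alone would give. MMP12 stood 3.24 higher in wide-range and 1.07 higher in narrow-range arrays, a difference of 2.17 with a limma adjusted p of 0.360. The MMP12 call lay at the edge of the threshold: with each array left out in turn its limma adjusted p ran from 0.00936 to 0.101 and missed the threshold in 44 of 92 fits, and under 20 alternatives it ran from 0.0234 to 0.998 and missed it in 8.

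Among the 31 gene lists fixed in advance, 9 stood higher in cancer over all 92 arrays by limma's camera test with a preset correlation of 0.01, and none stood lower. Hypoxia genes had a mean log2 difference of 0.53 (15 of 16 members positive, camera adjusted p = 1.04e-07, and adjusted p = 0.0996 with an estimated correlation). Neutrophil genes differed by 0.59 on average (16 of 16 positive, adjusted p = 1.99e-07, and adjusted p = 0.227 with an estimated correlation); they stood at 2.01 in wide-range arrays and at -0.032, with 6 of 16 positive, in the 64 narrow-range arrays. Inflammatory cytokine and NF-kB genes differed by 0.48 (14 of 18 positive, adjusted p = 7.19e-07, and adjusted p = 0.120 with an estimated correlation). Matrix protease genes, MMP12 among them, differed by 0.42 (14 of 16 positive, adjusted p = 4.47e-06, and adjusted p = 0.0487 with an estimated correlation). Cell cycle genes differed by 0.28 (20 of 23 positive, adjusted p = 7.16e-06, and adjusted p = 0.0929 with an estimated correlation). Monocyte and macrophage genes differed by 0.41 (11 of 12 positive, adjusted p = 9.52e-05, and adjusted p = 0.227 with an estimated correlation). Immediate early genes, induced within minutes of a stimulus, differed by 0.41 (16 of 17 positive, adjusted p = 0.000251, and adjusted p = 0.530 with an estimated correlation). Apart from MMP12, no member of these lists passed the test over all genes. Adjusted over the list alone, 2 of the 16 matrix protease genes, 2 of the 18 inflammatory genes and 1 of the 23 cell cycle genes passed, all higher, and no member of the neutrophil, macrophage, hypoxia or immediate early lists. When the labels were permuted on the mean of each list, no list passed (smallest adjusted p = 0.0511), nor did any in limma's fry test (smallest adjusted p = 0.0961). In the 64 narrow-range arrays no list passed camera (smallest adjusted p = 0.0633). Mean differences there were 0.30 for hypoxia, 0.20 for matrix protease and 0.15 for cell cycle genes. They were 0.13 for inflammatory, 0.12 for immediate early and 0.065 for monocyte and macrophage genes.

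In the 28 wide-range arrays, hypoxia genes were higher in cancer as a group. The list mean was 11.8 ± 0.473 in cancer and 10.8 ± 0.372 in non-cancer (log2 signal, SD, n = 16 and 12), a difference of 1.01. All 16 cancer arrays lay above the non-cancer median, and 13 lay above every non-cancer array. Of 16 measured members, 15 were positive, 4 passed the test over all genes and 11 did when adjusted over the list alone. The 4 were ADM, encoding the vasodilator peptide adrenomedullin (log2 difference 2.64, SE 0.570), LDHA, encoding lactate dehydrogenase A (1.54, SE 0.2995), VEGFA, encoding the angiogenic growth factor (1.39, SE 0.284), and NDRG1, a gene induced by low oxygen (1.25, SE 0.260), with limma adjusted p from 0.0355 to 0.0438. The list passed with camera (adjusted p = 1.29e-13), with an estimated correlation (adjusted p = 0.000650), with fry (adjusted p = 1.56e-05) and by permutation of the list mean (adjusted p = 0.000620 over 31 lists). With each of the 28 arrays left out in turn, those of the similar wide-range pair included, the difference stayed between 0.96 and 1.07, with a permutation p of at most 4e-05. In the same arrays the neutrophil list stood at 2.01, the monocyte and macrophage list at 1.19 and the luminal urothelium list at -0.72, and with the mean of the neutrophil and macrophage lists as a covariate the hypoxia difference was 0.76 (95% interval 0.47 to 1.05). In the narrow-range arrays the difference was 0.30 (permutation p = 0.203). The difference between the 2 kinds of array was 0.70, with a permutation p of 0.0433 and an adjusted p of 0.289 over 31 lists, so the effect was not shown to depend on the kind of array.

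Of single genes, 30 passed in the 28 wide-range arrays, 12 higher and 18 lower in cancer. The higher ones with the largest differences were MMP12 (log2 difference 3.24, SE 0.658, above the non-cancer median in 14 of 16 cancer arrays), HSPA6, a stress-inducible member of the HSP70 family (2.85, SE 0.586), and GJB2, encoding the gap junction protein connexin 26 (2.73, SE 0.561). HILPDA, a lipid droplet protein gene induced by hypoxia, rose by 2.06, SNAI2, encoding the transcription factor Slug, by 1.81, GADD45B by 1.71, DDIT4, an inhibitor of mTORC1 signalling, by 1.68, and ABCG1, a cholesterol transporter, by 1.42. The 12 higher genes had limma adjusted p from 0.0355 to 0.0491. With each read from 1 probe set, the other probe sets of ABCG1 past the filter stood at 0.14, 0.70 and 0.96. Those of GADD45B stood at 1.39, 1.85 and 0.95, that of HSPA6 at 2.60 and that of HILPDA at 2.58. The largest decreases were in SCUBE2, a secreted protein of hedgehog signalling (log2 difference -2.96, SE 0.528, limma adjusted p = 0.0275), and CWH43 (-2.36, SE 0.388, limma adjusted p = 0.0141). SLC46A2 (-2.27), CAPN8, encoding a calpain protease (-2.18), SHROOM1 (-2.03), AP1S3, PRAC1 (-1.91), ELF5, an epithelial ETS transcription factor (-1.70), ZMAT1 (-1.59), MTUS2 (-1.58), GLDN (-1.38) and CRACR2A (-1.29) were also lower. Each was read from 1 probe set. Other probe sets of these genes past the filter stood at 0.09 for CRACR2A, -0.20 and -1.01 for MTUS2, -0.69 for GLDN and -1.39 for SHROOM1. Below the filter, those of AP1S3 stood at -0.48, 0.09, 0.20 and -0.03, that of ZMAT1 at 0.29 and that of ELF5 at -0.93. Those of SHROOM1, CRACR2A, CWH43 and MTUS2 below the filter stood at 0.09, -0.04, -1.53 and -1.28, in that order. This count rested on the exact set of arrays: leaving out each of the 28 in turn gave between 1 and 45 genes, with a median of 2.5, and 18 of the 28 moved it by more than 1.5 times. With limma 0 genes passed at a ratio above 16 or above 64 and with the mean of the neutrophil and macrophage lists as a covariate, and 0 passed in a Wilcoxon test (1043 to 1810 at an unadjusted p under 0.05 in these 4), while a pseudocount of 1 gave 2, centring on the median 16 (11 higher, 5 lower) and array weights 82.

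**Figure D2:**
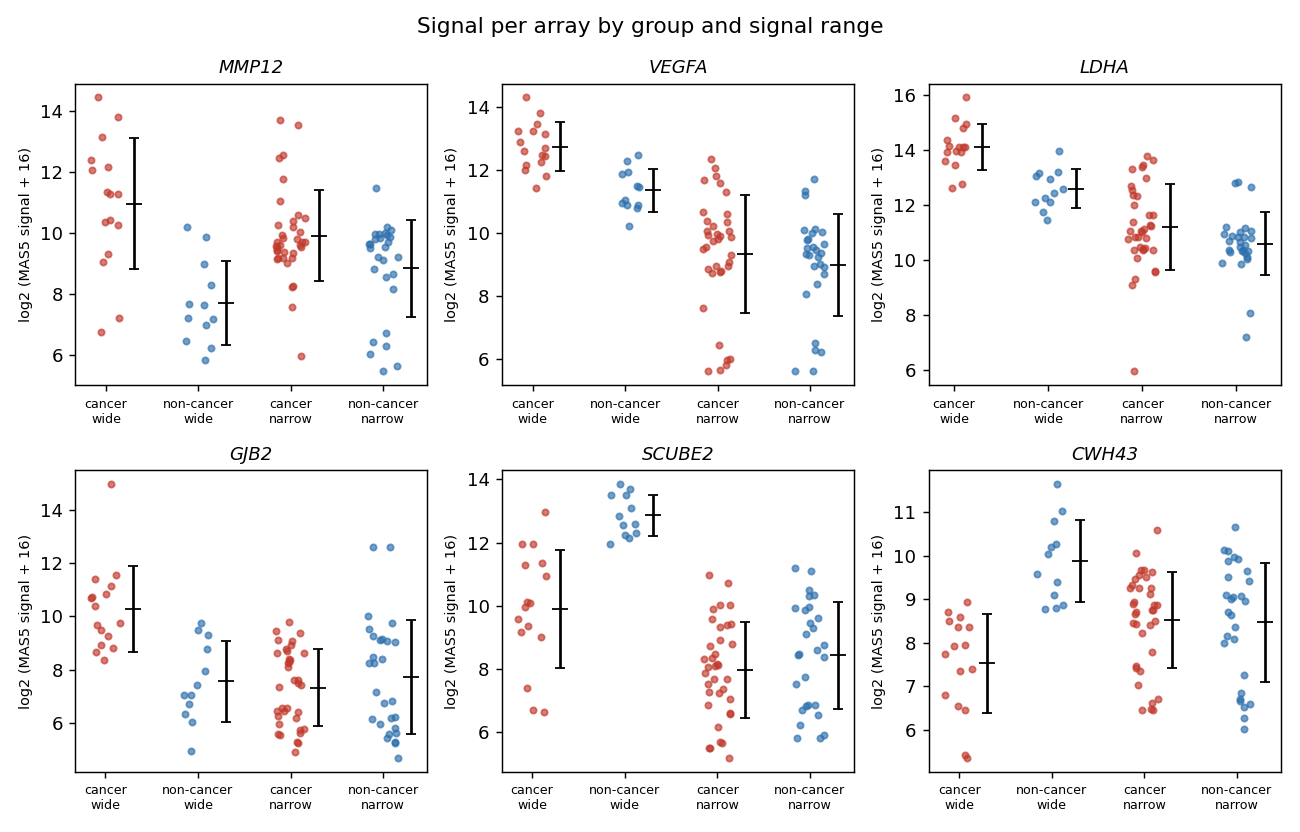
Log2 (MAS5 signal + 16) of 6 genes in each array, by group and by signal range, with the mean and SD of each set as a bar beside the points (16 cancer and 12 non-cancer wide-range arrays, 36 and 28 narrow-range arrays). In wide-range arrays MMP12, VEGFA, LDHA and GJB2 were higher in cancer, by 3.24, 1.39, 1.54 and 2.73, and SCUBE2 and CWH43 were lower, at -2.96 and -2.36.

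Myeloid and luminal urothelium lists had mean differences of opposite sign in the wide-range arrays, and none of these calls held with an estimated correlation. Neutrophil genes were 2.01 higher in cancer on average, with S100A8 and S100A9, the calprotectin subunits, at 2.89 and 2.75. Monocyte and macrophage genes were 1.19 higher, with CD14 at 1.98 and the mannose receptor MRC1 at 1.80. The T and NK cell list had a mean difference of -0.42 (1 of 12 members positive, camera adjusted p = 0.103), and the basal urothelium list one of 0.31 (7 of 10 positive, camera adjusted p = 0.278). Luminal urothelium genes, expressed in the differentiated lining of the bladder, had a mean difference of -0.72, and 1 of 22 members was positive. Uroplakins UPK3A and UPK1A stood at -2.13 and -1.88, and KRT20 at 1.43. None of these genes passed limma's test over all genes; adjusted over the list alone, 3 neutrophil genes and 1 macrophage gene were higher and 2 luminal genes lower. By camera the neutrophil (adjusted p = 4.19e-11), monocyte and macrophage (adjusted p = 4.57e-06) and luminal (adjusted p = 1.56e-05) lists passed, and with an estimated correlation none did (adjusted p = 0.240, 0.355 and 0.393). By permutation of the list mean the adjusted p was 0.106 for neutrophils, 0.178 for monocytes and macrophages and 0.170 for luminal urothelium.

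Other lists that passed camera in the wide-range arrays were inflammatory cytokines and NF-kB genes (mean log2 difference 1.28, with CXCL8 at 3.29), immediate early genes (1.02, with IER3 at 2.03), matrix proteases (0.96), cell cycle genes (0.59, with TOP2A at 1.26), genes of the epithelial to mesenchymal transition (0.55), squamous and cornified envelope genes (0.46, with SPRR1B at 2.72), p53 targets (0.32) and cytosolic ribosomal proteins (-0.33, with RPS14 at -0.56). With an estimated correlation none of these passed, with adjusted p of 0.240, 0.240, 0.240, 0.294, 0.393, 0.591, 0.264 and 0.518 in that order. Lists whose mean and median differed in sign in these arrays were MHC class II, unfolded protein response and genes often altered in bladder tumours, and none of them passed.

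**Figure D3:**
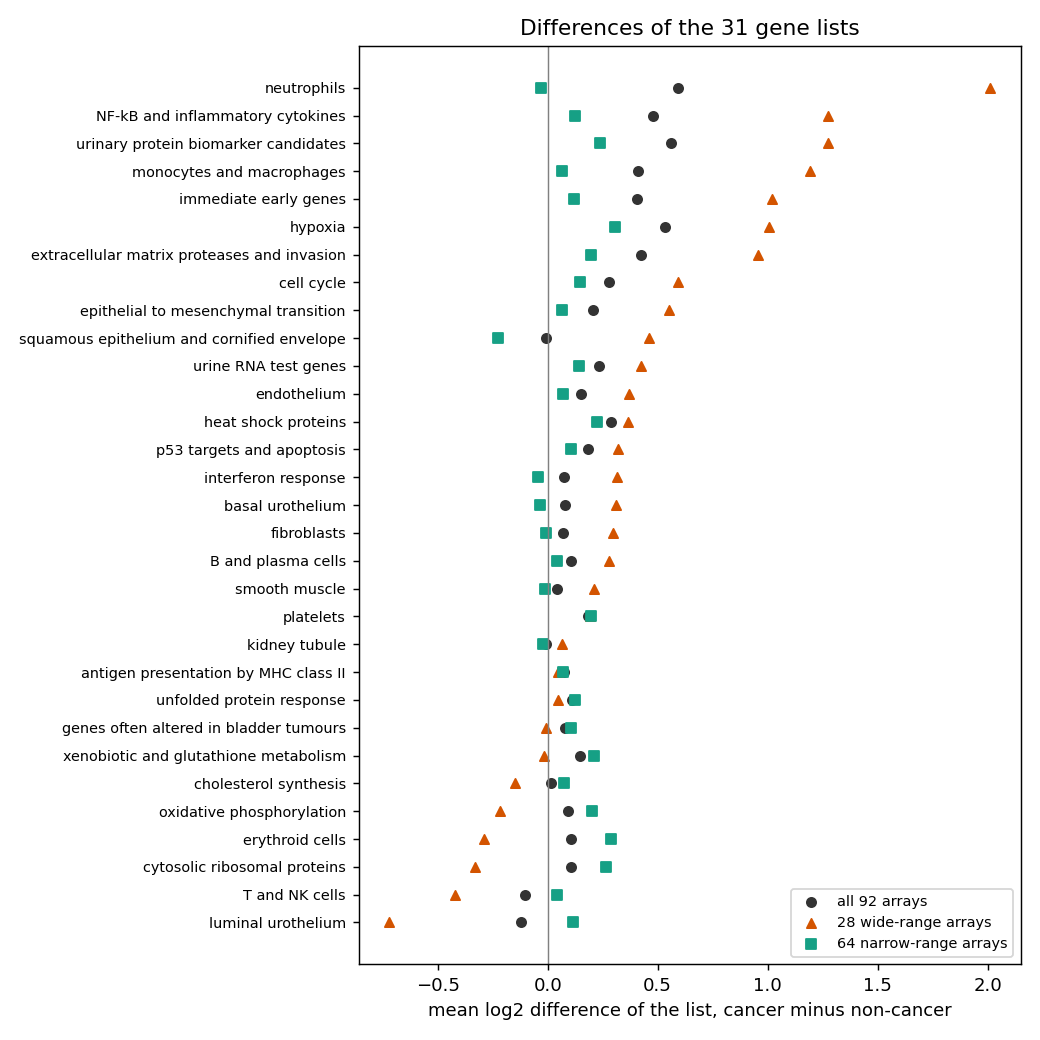
Mean log2 difference of each of the 31 gene lists, cancer minus non-cancer, in all 92 arrays, the 28 wide-range arrays and the 64 narrow-range arrays. In wide-range arrays the list means run from -0.72 for luminal urothelium to 2.01 for neutrophils, and hypoxia stands at 1.01.

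Of the genes used in urine protein assays, 11 of 14 were measured. Over all 92 arrays they had a mean log2 difference of 0.56 (10 of 11 positive, camera adjusted p = 1.98e-06, and adjusted p = 0.0487 with an estimated correlation), and none passed over all genes while 2 did when adjusted over the list alone. The values were CXCL8 1.37, CCL18 1.08, APOE 0.70, MMP9 0.69, VEGFA 0.68, SPP1 0.61, PTX3 0.50, CD44 0.36, SDC1 0.28, SERPINA1 0.18 and ANG -0.30. In wide-range arrays the list mean was 1.27 higher, VEGFA passed over all genes and 6 members passed when adjusted over the list alone (camera adjusted p = 2.42e-06, and adjusted p = 0.0752 with an estimated correlation). The candidates were drawn up from general knowledge, partly of urine profiling by the same investigators, so the list is not independent evidence of its direction. Of the genes used in urine RNA tests, 12 of 16 were measured, with a mean difference of 0.23 over all arrays (8 of 12 positive, camera adjusted p = 0.0248, and adjusted p = 0.0929 with an estimated correlation). The cell division gene CDC20 (0.90), KRT20 (0.85), ANXA10 (0.63), CDK1 (0.54), CXCR2 (0.49), FGFR3 (0.33), TERT (0.17) and MDK (0.05) had positive values, and BIRC5 (-0.07), KRT5 (-0.15), UPK1B (-0.27) and IGFBP5 (-0.69) negative ones. None of the 12 passed over all genes, and 1 did when adjusted over the list alone. The values are those of 1 probe set per gene, and the other 3 probe sets of BIRC5 stood at 0.21, 0.21 and 0.11. Those of IGFBP5 past the filter, other than the probe set used, stood at -0.96, 0.013 and -0.37. In wide-range arrays the list had a mean difference of 0.42 (10 of 12 positive, camera adjusted p = 0.0579) and did not pass. IGFBP5, lower at -2.46, was the 1 member that passed there when adjusted over the list alone. Its other probe sets past the filter stood at -2.14, -0.20 and -0.36 there. KRT5 stood at 1.23 and did not pass.

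The area under the ROC curve (AUC) describes how far the groups overlap on a gene. For MMP12 it was 0.743 over all 92 arrays, on the samples from which the gene was picked, and 0.896 in the wide-range arrays. A signature fitted by penalized logistic regression, with every gene selection inside the training samples, gave an AUC on held-out samples of 0.648 ± 0.0397 (SD over 10 repeats) and held a median of 20.5 genes. Of 100 permutations of the labels, run once each, 3 reached that AUC (permutation p = 0.0396), and their median was 0.488. The AUC was 0.826 on the wide-range arrays and 0.565 on the narrow-range arrays. A random forest on the same folds gave 0.590, quantile-normalized values gave 0.577 and the urine protein candidates alone gave 0.630.

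Within the cancer samples, the mean of the neutrophil list and that of the luminal urothelium list showed no relation past the threshold over all 52 arrays (Pearson r = 0.110, permutation p = 0.438; Spearman rho = 0.274, permutation p = 0.05003; r = 0.242 without the 2 arrays farthest from the median; adjusted p = 0.525 over 6 relations). The sign differed between the 2 kinds of array, the difference of the correlations itself was not tested, and both the pooled values and those in narrow-range arrays changed given the control 3'/5' ratio. No correlation was adjusted for the signal range, which went from 7.28 to 28.02 among narrow-range arrays. A rise of both lists with the range was therefore not set apart from a relation between them. In the 16 wide-range cancer arrays r was -0.742 (permutation p = 0.000150, adjusted p = 0.000660; rho = -0.700, permutation p = 0.00383; r = -0.652 without the 2 farthest arrays). In the 36 narrow-range cancer arrays r was 0.586 (permutation p = 0.000220, adjusted p = 0.000660; rho = 0.671, permutation p = 2e-05; r = 0.612 without the 2 farthest arrays). In non-cancer samples r was -0.147 over all 40 arrays (permutation p = 0.369, adjusted p = 0.525; rho = -0.233, permutation p = 0.151; r = -0.174 without the 2 farthest arrays). In the 12 wide-range non-cancer arrays r was -0.578 (permutation p = 0.0466, adjusted p = 0.0932; rho = -0.503, permutation p = 0.0982), and without the 2 farthest arrays it was -0.224, so this relation rested on those samples. In the 28 narrow-range non-cancer arrays r was 0.124 (permutation p = 0.533, adjusted p = 0.533; rho = -0.167, permutation p = 0.393; r = -0.0882 without the 2 farthest arrays).

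Given the control 3'/5' ratio of each array, the neutrophil and luminal lists had a negative r over all 52 cancer arrays, -0.381 (permutation p = 0.00616, adjusted p = 0.0123 over 6 relations; rho = -0.173, permutation p = 0.221; r = -0.272 without the 2 farthest arrays). Over all 40 non-cancer arrays it was -0.488 (permutation p = 0.00163, adjusted p = 0.00489; rho = -0.370, permutation p = 0.0197; r = -0.423 without the 2 farthest arrays). In wide-range arrays it was -0.778 in cancer (permutation p = 0.000140, adjusted p = 0.000840; rho = -0.774, permutation p = 0.000840; r = -0.684 without the 2 farthest arrays). In wide-range non-cancer arrays it was -0.626 (permutation p = 0.0268, adjusted p = 0.0321; rho = -0.545, permutation p = 0.0701), and at -0.243 without the 2 farthest arrays it rested on those samples. In narrow-range cancer arrays it was 0.144 (permutation p = 0.403, adjusted p = 0.403; rho = 0.244, permutation p = 0.152; r = 0.213 without the 2 farthest arrays). In narrow-range non-cancer arrays it was -0.422 (permutation p = 0.0256, adjusted p = 0.0321; rho = -0.408, permutation p = 0.0316; r = -0.482 without the 2 farthest arrays).

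**Figure D4:**
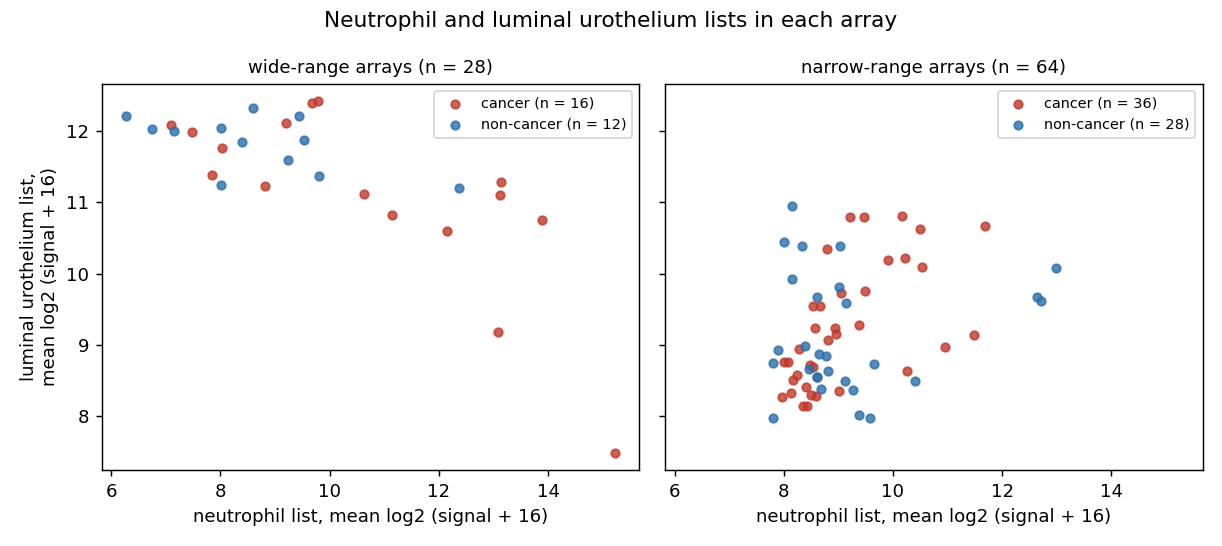
Mean log2 (signal + 16) of the neutrophil list against that of the luminal urothelium list, a point per array, for 28 wide-range and 64 narrow-range arrays. Among cancer samples the correlation was -0.742 in wide-range and 0.586 in narrow-range arrays, and given the control 3'/5' ratio -0.778 and 0.144. None of these values was adjusted for the signal range.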

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

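The interaction tests and the tests in wide-range arrays were chosen after the data were seen, since these kinds of array were defined from the data.

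For 6 genes the difference between cancer and non-cancer was itself different in wide-range and narrow-range arrays, by limma's interaction term over 15210 genes. The interaction was -2.68 for CAPN8 (limma adjusted p = 0.0370), -2.40 for CWH43 (limma adjusted p = 0.0445), -2.20 for DEPTOR, an inhibitor of mTOR (limma adjusted p = 0.0149), -1.99 for POPDC1 (limma adjusted p = 0.0353), -2.44 for PROM1, which encodes the surface protein CD133 (limma adjusted p = 0.0308), and 2.34 for TMEM45A (limma adjusted p = 0.0149). DEPTOR, POPDC1, PROM1 and TMEM45A were named after their values were seen. Wide-range and narrow-range arrays are not groups of the study.

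Probe sets without exactly 1 gene symbol entered no comparison of genes. In the wide-range arrays 27 of all 35619 probe sets passed limma's test, and 7 of the 8730 without exactly 1 symbol did, a similar share. Of the 8730, 655 had an unadjusted p under 0.05 there, above the share of 0.05 that chance alone would give. Over all 92 arrays 0 passed with limma, and 216 had an unadjusted p under 0.05, below that share.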

How the results depend on the processing

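The settings on wide-range and narrow-range arrays, the limits on the range, the array range as a covariate or block, the permutation of list means, leaving out each array and leaving out 1 of the 2 most similar arrays were chosen after seeing the data; the others were planned. The number of arrays and the narrow signal range of 64 of them limit what can be seen. For every result below that changed, the cause was not tested.

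The single gene over all 92 arrays became 0 with limma after quantile normalization, with no filter, with every probe set, with array quality weights, with the mean of the neutrophil and macrophage lists as a covariate, without the 10 arrays with the highest 3'/5' ratio and with a replicate block, and 0 with a Wilcoxon rank-sum test (414 to 1109 at an unadjusted p under 0.05 in these 8). It was 30 in wide-range arrays only, and in narrow-range arrays the 1 gene was a different one. The replicate block gave 13 lists, 9 higher and 4 lower; samples with a shared number had a median r of 0.0753 and others 0.0515, a difference that was not tested, and 3 of 40 cancer samples were most like the non-cancer sample of their own number, so a paired design was not shown. Leaving out each array gave 0 to 1 genes. It gave 0 without cancer samples 8, 13, 18, 23, 24, 26, 27, 28, 29, 31, 32, 34, 35, 36, 37, 41, 42, 43, 44, 45, 47, 48, 49, 51 and 52 and without non-cancer samples 1, 2, 3, 4, 8, 9, 12, 13, 14, 18, 19, 20, 21, 25, 34, 35, 36, 38 and 39.

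The 30 genes of the wide-range arrays became 0 at a limit of 16 times the median, 4 at the next limit tried, 0 at 64 times, 16 with each array centred on its median, 2 with pseudocount 1, 82 with array quality weights, 0 with a Wilcoxon rank-sum test, 49 with the array range as a covariate and 0 with the mean of the neutrophil and macrophage lists as a covariate (1043 to 1810 at an unadjusted p under 0.05 in the 4 settings with 0). Leaving out each array gave 1 to 45 genes. The count moved by over 1.5 times without cancer samples 8 (to 1), 24 (2), 35 (2), 37 (2), 41 (2), 43 (2), 44 (1) and 47 (18), and without non-cancer samples 14 (1), 19 (2), 20 (1), 21 (2), 25 (1), 35 (1), 36 (1), 37 (10), 38 (3) and 39 (5).

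The 9 lists became 2 with an estimated correlation and 0 in narrow-range arrays only, with fry (directional or mixed) and by permutation of the list mean. The hypoxia difference of wide-range arrays was 0.30 in narrow-range arrays and between 0.96 and 1.07 with each array left out. The AUC of MMP12 was 0.896 in wide-range arrays. The AUC of the signature was 0.577 after quantile normalization, 0.590 with a random forest, 0.826 on wide-range and 0.565 on narrow-range arrays. The neutrophil and luminal correlation in cancer was -0.742 in wide-range and 0.586 in narrow-range arrays. Given the control 3'/5' ratio it was -0.381 over all cancer arrays and passed, and 0.144 in narrow-range cancer arrays, where it no longer passed. In non-cancer it was -0.488 given that ratio, where it passed, 0.127 with monocytes and macrophages in place of neutrophils, -0.578 in wide-range and 0.124 in narrow-range arrays.

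Among named genes not past the threshold, some changed sign. BIRC5 was 0.020 with the mean of all probe sets, 0.25 with the replicate block and 0.16 in wide-range arrays, where KRT5 was 1.23. SERPINA1 was -0.14 without _s_at and _x_at probe sets, -0.013 with array quality weights and -0.29 with the neutrophil and macrophage covariate, where CD44 was -0.0092. With the replicate block CD44 was -0.27 and SDC1 -0.031. In narrow-range arrays CXCR2 was -0.024, IGFBP5 0.062, MDK -0.024, SERPINA1 -0.49, SPP1 -0.0088 and the neutrophil list -0.032. Without 1 of the 2 most similar arrays 1 gene passed over all arrays (MMP12, limma adjusted p = 0.0346) and 10 lists, 9 of them shared, and the AUC of the signature was 0.618. Of the values of named genes over all arrays, 533 kept their direction and side of the threshold, 8 fell short of it, 1 newly passed and 15 changed sign; of those in wide-range arrays 181 kept them and 155 fell short; of those of lists 60 kept them, 47 fell short and 1 changed sign.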

Other observations

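In this part, the test of disease group against signal range, the part of a difference that goes with the 3'/5' ratio or with the array range, and the tests that use the division into wide-range and narrow-range arrays were chosen after the data were seen.

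In the narrow-range arrays a single gene passed, GNA14, encoding a G protein subunit, at 1.38 (limma adjusted p = 0.0488). It stood at -0.16 in the wide-range arrays, and it was named after its value was seen.

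The call of 1 gene over all 92 arrays was equalled in 2 of 100 splits of the arrays into 52 and 40, the real one included, and the highest other count was 1. For a count of 1 gene this share adds little to MMP12's limma adjusted p of 0.0446 and does not exclude chance. The call was also lost in 44 of 92 fits with an array left out. In the 28 wide-range arrays, 2 of 100 splits into 16 and 12 gave at least the real 30 genes. The highest other split gave 58, above the real count. The share of 2 in 100 lies under 0.05 by a thin margin, but these splits do not repeat the choice of limit. This limit was kept where the others tried gave 0 and 4 genes, so the share does not exclude chance. In another 100 permutations, over all 92 labels and taking the highest count over the 3 limits tried, 1 gave as many as 30, the real one itself, and the highest other count was 2. A highest count over limits cannot lie under that at 1 of them for the same labels, so the smaller share comes from other draws and does not make the result firmer.

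The narrow range of 64 of 92 arrays went with a high signal of the bacterial controls added before hybridisation. Across arrays the Spearman rho between range and the mean log2 signal of 11 such probe sets was -0.859 in cancer (permutation p = 1e-05, the smallest the permutations can give; Pearson r = -0.909, permutation p = 1e-05, r = -0.893 without the 2 farthest arrays) and -0.868 in non-cancer (permutation p = 1e-05; r = -0.907, permutation p = 1e-05, r = -0.882 without the 2 farthest arrays), with an adjusted p of 1e-05 for both r over 2 relations. The 3'/5' log2 ratio of control probe sets, a sign of RNA quality, was also higher in wide-range arrays (4.17 ± 0.961 against 2.55 ± 1.23, SD, n = 28 and 64), and whether the range follows it was not tested. Little labelled RNA relative to the controls is a candidate explanation of the narrow range, as a hypothesis, because scaling to a fixed mean raises the controls where other signal is weak. The disease group is argued against as its origin, with an odds ratio of 1.04 (95% interval 0.387 to 2.83) for a wide range in cancer, and no other biological explanation was tested.

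The higher hypoxia genes of cancer in wide-range arrays were set against cell composition and RNA degradation. With the mean of the neutrophil and macrophage lists as a covariate the difference went from 1.01 (95% interval 0.67 to 1.35) to 0.76 (0.47 to 1.05). Part of the difference may thus go with leukocytes. That mean reads the share of leukocytes imperfectly, so the adjustment may remove too little. It does not decide whether leukocytes are the whole cause. The control 3'/5' ratio differed little between the groups (-0.0897, 95% interval -0.866 to 0.686), so adjusting for it could move little: the part of the difference that goes with it was -0.0069 (bootstrap interval -0.090 to 0.095), which argues against a group difference in that ratio as the cause, and not against degradation that the ratio does not read. Low oxygen in tumours remains a hypothesis, as do cell types not covered by the 2 lists, and neither was tested.

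For MMP12 over all 92 arrays the difference was 1.73 (95% interval 1.02 to 2.44). With the mean of the monocyte and macrophage list as a covariate it was 1.36 (0.80 to 1.93). The groups differed by 0.41 on that mean, which reads the number of macrophages imperfectly. The adjustment may therefore remove too little, and it does not decide whether their number is the whole cause. The range was close to balanced between the groups (difference 0.0886, -0.474 to 0.652), and the part of the MMP12 difference that goes with it was 0.0077 (-0.062 to 0.157), which argues against unequal ranges in the groups as its origin. It does not address the difference between 3.24 in wide-range and 1.07 in narrow-range arrays. The number of macrophages stays open as a possible explanation of the MMP12 difference. So do a change in their state and expression in tumour cells, neither of which was tested.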
